A study of Mus musculus with 5 samples.

How the data were processed

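Gene expression was measured by RNA sequencing of lineage-negative, c-Kit-high, Sca-1-positive, CD135-negative cells sorted from C57BL/6 mice, with 3 libraries from normal (naive) mice and 2 from mice with GVHD. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a SureSelect kit. The submitters' processing notes name TopHat, Cufflinks and Cuffdiff and the build mm10, with no versions, order or settings. The deposited table gives FPKM per gene and library, per the file headers and the name of its sheet. The gene annotation, strandedness and any scaling between libraries are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

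The table held 47781 rows. Of these, 1108 joined the symbols of several overlapping or merged genes, and 87 repeated a symbol. Values of a repeated symbol were summed, which gave 47694 features. Features with a mean of at least 1 FPKM over the 5 libraries were tested (23425, of which 958 were merged loci). Gene types, lengths and positions came from GENCODE vM21 on the mm10 assembly, in which 92.2% of the tested symbols were found. No 2 libraries held identical values. Read depth is unknown: low values of single-exon genes were checked for whole multiples of 1 read, and at best 25.3% to 28.2% per library lay within 0.1 of a whole number, where chance gives 20%. No counting interval is therefore given. In all, 6 protein-coding genes stood at 0 in 1 library and at 10 FPKM or more in the other 4.

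Values were transformed as log2(FPKM + 1) and fitted in limma 3.58.1 (R 4.3.3) with a group term and a moderated test with a mean-variance trend. All p-values are two-sided and were adjusted by Benjamini-Hochberg over all tested features, with a threshold of 0.05. Each log2 difference is GVHD minus naive. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists with at least 5 tested members, and beside it with camera's estimated correlation and with fry. Members in merged loci were left out. The sex-linked list (4 tested members) and the mitochondrial list, whose genes all lay in merged loci, were not tested. Some lists share members: the quiescence list shares Nr4a1 and Klf6, among others, with the immediate early list and Cdkn1c, among others, with the HSC list, and lymphoid priming shares Ighm and Cd79a, among others, with the B and plasma cell list. The 5 libraries allow 10 splits into 3 and 2, so an exact permutation test of a list median cannot go below p = 0.1. Of the 20 lists that passed camera, 10 reached that value. For the rest, p was 0.2 for the HSC identity, immediate early, S phase, histone, MHC class I and antioxidant lists. It was 0.3 for the neutrophil and type I interferon lists and 0.5 for the ribosomal protein and adhesion lists.

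Named genes followed a rule set before the data were examined. It took up to 10 genes in each direction with the largest log2 difference among those that passed, with groups that did not overlap and at least 5 FPKM in the higher group. Predicted models, microRNAs, small nucleolar RNAs and pseudogenes were left out by their symbols. Short rRNA models and a model with a clone name do not carry such symbols, so they stayed in. It also took the 4 members with the smallest p of each list that passed, the 2 most abundant members of the other described biology lists, Kit, Ly6a, Flt3, the tested mature pDC markers, the sex-linked genes and the most abundant member of each cell type list. Genes named outside this rule were chosen after their values were seen. They were the globin genes, Malat1, Mir6240, Rn18s-rs5, Lars2, Gm17428, the merged loci, the class-switched immunoglobulin genes and the genes that open the other observations. The plasma cell genes Sdc1, Prdm1 and Tnfrsf17 were also chosen in this way.

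Both procedures were tested on simulated data with the real means and moderated spreads of the 23425 features. Of 200 features changed by a log2 difference of 1, 2 or 4, limma recovered 0%, 0% and 16.7%. In all, limma called 14 features, of which 3 were unchanged, a larger share than the adjusted p threshold aims for. Camera recovered a list of independent genes shifted by 1 (adjusted p = 1.48e-06), and called 0 of 38 unchanged lists. The unchanged lists also held independent genes. In the real lists that passed, the estimated correlation ran from 0.07 (lymphoid priming) to 0.95 (MHC class I presentation). The simulation therefore does not measure false calls among correlated genes. Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, rescaling to equal sums, upper quartile scaling, quantile normalization, no trend, robust variance shrinkage, array weights, replicate number as a block, each library left out, and for genes a threshold of 0.1, a minimum log2 difference and leaving out repeated symbols. No GVHD library is numbered 2, so the replicate block takes naive replicate 2 out of the group contrast. A fit to protein-coding genes alone was added after the data were seen.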

Results

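Bulk RNA sequencing measured gene expression in mouse bone marrow stem and early progenitor cells, sorted as lineage-negative, c-Kit-high, Sca-1-positive and CD135-negative. The cells came from C57BL/6 mice that were normal (naive, 3 libraries, replicates 0, 1 and 2) or had graft-versus-host disease (GVHD, 2 libraries, replicates 0 and 1). The series title places the comparison in a study of how donor plasmacytoid dendritic cells (pDCs) are rebuilt during GVHD, and these sorted cells lie upstream of that lineage. A transplanted group without GVHD was not analysed here, so transplantation and GVHD were compared together against the normal state. The labels used here do not say whether the GVHD cells were of donor or host origin. Nothing in the labels says that the libraries came from separate animals, and p-values measure only the spread between these samples, which may be technical.

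The values were FPKM (fragments per kilobase, scaled to the mapped fragments of each library), and read depth is unknown. Column sums were 1087534, 1067125 and 797131 FPKM in naive replicates 0, 1 and 2 and 1547607 and 1620622 in GVHD replicates 0 and 1. The microRNA precursor model Mir6240 alone stood at 55709, 38301 and 3207 FPKM in the naive libraries and at 237479 and 283083 in the GVHD libraries. The 18S rRNA model Rn18s-rs5 moved the same way (11727, 11668 and 3850 FPKM in naive, 23896 and 33369 in GVHD libraries). So did Lars2 (5751, 5952 and 976, and 24477 and 13713). The source of the reads assigned to these features was not tested. The nuclear RNA Malat1 stood at 14832 FPKM in naive replicate 2, against 3882 and 4293 in the other naive libraries and 840 and 1408 in the GVHD libraries. The Y-linked genes Ddx3y and Eif2s3y were at 15.3 and 19.97 FPKM in GVHD replicate 0, and no other library exceeded 0.507 FPKM for either. The merged locus that contains Xist, the X-inactivation transcript, stood at 143, 126 and 152 FPKM in the naive libraries and at 21.4 and 54.7 in GVHD replicates 0 and 1. Uty was at 8.12 FPKM in GVHD replicate 0 and between 0.811 and 1.21 in the other libraries, while Kdm5d, which has a close X-linked copy, lay between 2.12 and 5.52 in all 5.

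**Figure D1:**
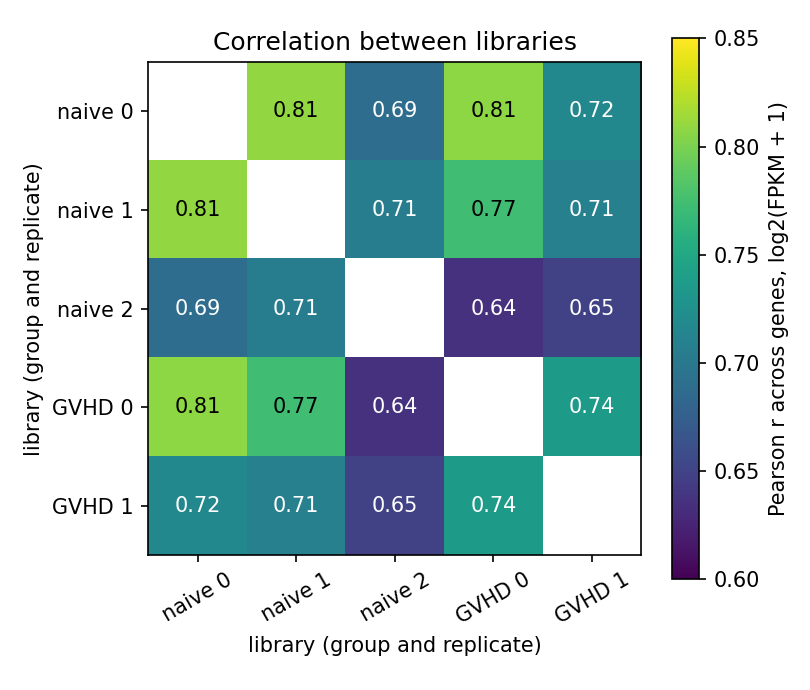
Pearson correlation of log2(FPKM + 1) across the tested genes for each pair of libraries, with libraries named by group and replicate on both axes. GVHD replicate 0 correlated more closely with naive replicate 0 (0.81) than with GVHD replicate 1 (0.74), and naive replicate 2 had the lowest values (0.64 to 0.71).

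In the GVHD cells, genes of the erythroid and mast cell lineages and interferon gamma target genes were higher, and so were genes of cell division, nucleolar function and respiration. Genes that mark hematopoietic stem cells (HSCs), quiescence, lymphoid priming and the immediate early response were lower, as were transcripts of B and plasma cells. The lymphoid priming list shares members with the B and plasma cell list and is not a separate result from it. These statements rest on 41 gene lists fixed before the data were examined, of which 39 were tested and 20 passed (13 higher and 7 lower, limma's camera with a preset correlation, adjusted p at most 0.05). None of the 20 passed when camera estimated the correlation between genes from these 5 libraries (lowest adjusted p = 0.581), and none passed fry's directional test (lowest adjusted p = 0.147, with 6 of the 20 at an unadjusted p of at most 0.05). List medians below are log2 differences, GVHD minus naive, relative to the median of all tested genes, which was -0.04. For HSC identity, immediate early and S phase genes, another split of the libraries gave a median at least as far from 0 (exact permutation p = 0.2).

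Erythroid genes rose most. The list had a median of 2.32 over 28 tested members, and 20 members lay above every naive library in both GVHD libraries, where chance gives 10% of genes (camera adjusted p = 1.06e-18, but 0.581 with an estimated correlation). Chance here means equally likely splits of the libraries. The observed share over all tested genes is not given, for this or the later lists. Adjusted over the list alone, 20 members passed, and 1 passed when adjusted over all genes. That gene, Rhag, which encodes the Rh-associated glycoprotein of the red cell membrane (chromosome 17, 40811126 to 40840754, mm10), rose 22.3-fold, from 0.955 ± 0.274 FPKM (SD, n = 3) to 21.2 ± 6.78 (SD, n = 2), with a limma adjusted p of 0.0493. The call of Rhag was lost in each of the 5 fits that left out a library (adjusted p = 0.0761 to 0.172) and in 14 of 18 other settings in all. Ermap, an erythroblast membrane protein, averaged 3.19 ± 1.88 FPKM in naive and 56.3 ± 9.40 in GVHD cells (log2 difference 3.87 ± 0.48 SE, adjusted p = 0.0797). Sphk1, a sphingosine kinase, and Ank1, the red cell ankyrin, had log2 differences of 3.53 and 3.01 (adjusted p = 0.0601 and 0.0961). Globin transcripts did not follow this pattern: Hba-a1, Hba-a2 and Hbb-bs had log2 differences of -0.42, -0.66 and -0.61, and Hbb-bt one of 1.03, with limma adjusted p-values from 0.815 to 0.912. The list median was 2.07 without GVHD replicate 0 and 2.43 without GVHD replicate 1.

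The mast cell and basophil list, a check for cells of another type, rose with the erythroid list (median 1.85 over 13 members, adjusted p = 2.86e-07, but 0.581 with an estimated correlation). Adjusted over the list alone, 7 members were higher and 1 was lower, and none passed over all genes. Cma1, a mast cell chymase, was at 27.8 and 27.0 FPKM in the GVHD libraries and at 2.44 to 3.49 in the naive ones (adjusted p = 0.0526). The tryptase Tpsb2, the IL-33 receptor gene Il1rl1 and the IgE receptor gene Fcer1a had log2 differences of 2.64, 2.18 and 2.05, while Srgn, the most abundant member, had one of -0.14. The list median was 0.90 without GVHD replicate 0.

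Interferon gamma target genes rose together (median 1.46 over 24 members, adjusted p = 1.21e-14, but 0.581 with an estimated correlation). Of these, 21 were higher in both GVHD libraries than in every naive library, and 7 passed when adjusted over the list alone. Iigp1, an interferon-inducible GTPase, averaged 5.23 ± 1.66 FPKM in naive and 54.7 ± 1.13 in GVHD cells (log2 difference 3.19 ± 0.36 SE, adjusted p = 0.0595). Gbp2, a guanylate-binding protein, averaged 10.2 ± 2.37 and 73.8 ± 7.30 FPKM (adjusted p = 0.0849), and the chemokine gene Cxcl10 1.48 ± 0.306 and 17.8 ± 9.67 (adjusted p = 0.147). Gm4951, another interferon-inducible GTPase, had a log2 difference of 2.06. In all, 11 list members, among them Igtp, lay in merged loci and were left out of the test. The locus that contains Igtp averaged 7.14 and 46.8 FPKM in naive and GVHD cells. The list median was 0.92 without GVHD replicate 0.

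The type I interferon list passed narrowly (median 0.14 over 31 members, adjusted p = 0.0385, but 0.711 with an estimated correlation) and lost its call in 9 of 18 other settings, with a median of 0.24 without GVHD replicate 1. Its members with the smallest p-values were higher in GVHD: Zbp1, Oasl1, Isg15 and Cmpk2 had log2 differences of 1.97, 1.62, 1.65 and 1.15, none past the threshold adjusted over the list alone. The list was mixed, with 17 positive and 14 negative differences. Its median lay at percentile 74.5 of random lists matched on mean expression, which a shift shared by genes of similar level could also give. MHC class I presentation genes had a median of 0.79 over 17 members (adjusted p = 7.00e-05, but 0.711 with an estimated correlation). H2-Q7, H2-Q6, Tapbpl and H2-T24 had log2 differences of 1.38, 1.09, 0.87 and 0.73, and the H2-Q genes are close copies whose reads may be shared. The class I median was 0.10 without GVHD replicate 0, where the call was lost, and 1.504 without GVHD replicate 1. The MHC class II list did not pass (adjusted p = 0.222), with H2-Ab1 at 41.8 ± 24.7 and 118 ± 38.8 FPKM and H2-Aa at 23.5 ± 18.5 and 61.2 ± 22.7 FPKM in naive and GVHD cells.

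**Figure D2:**
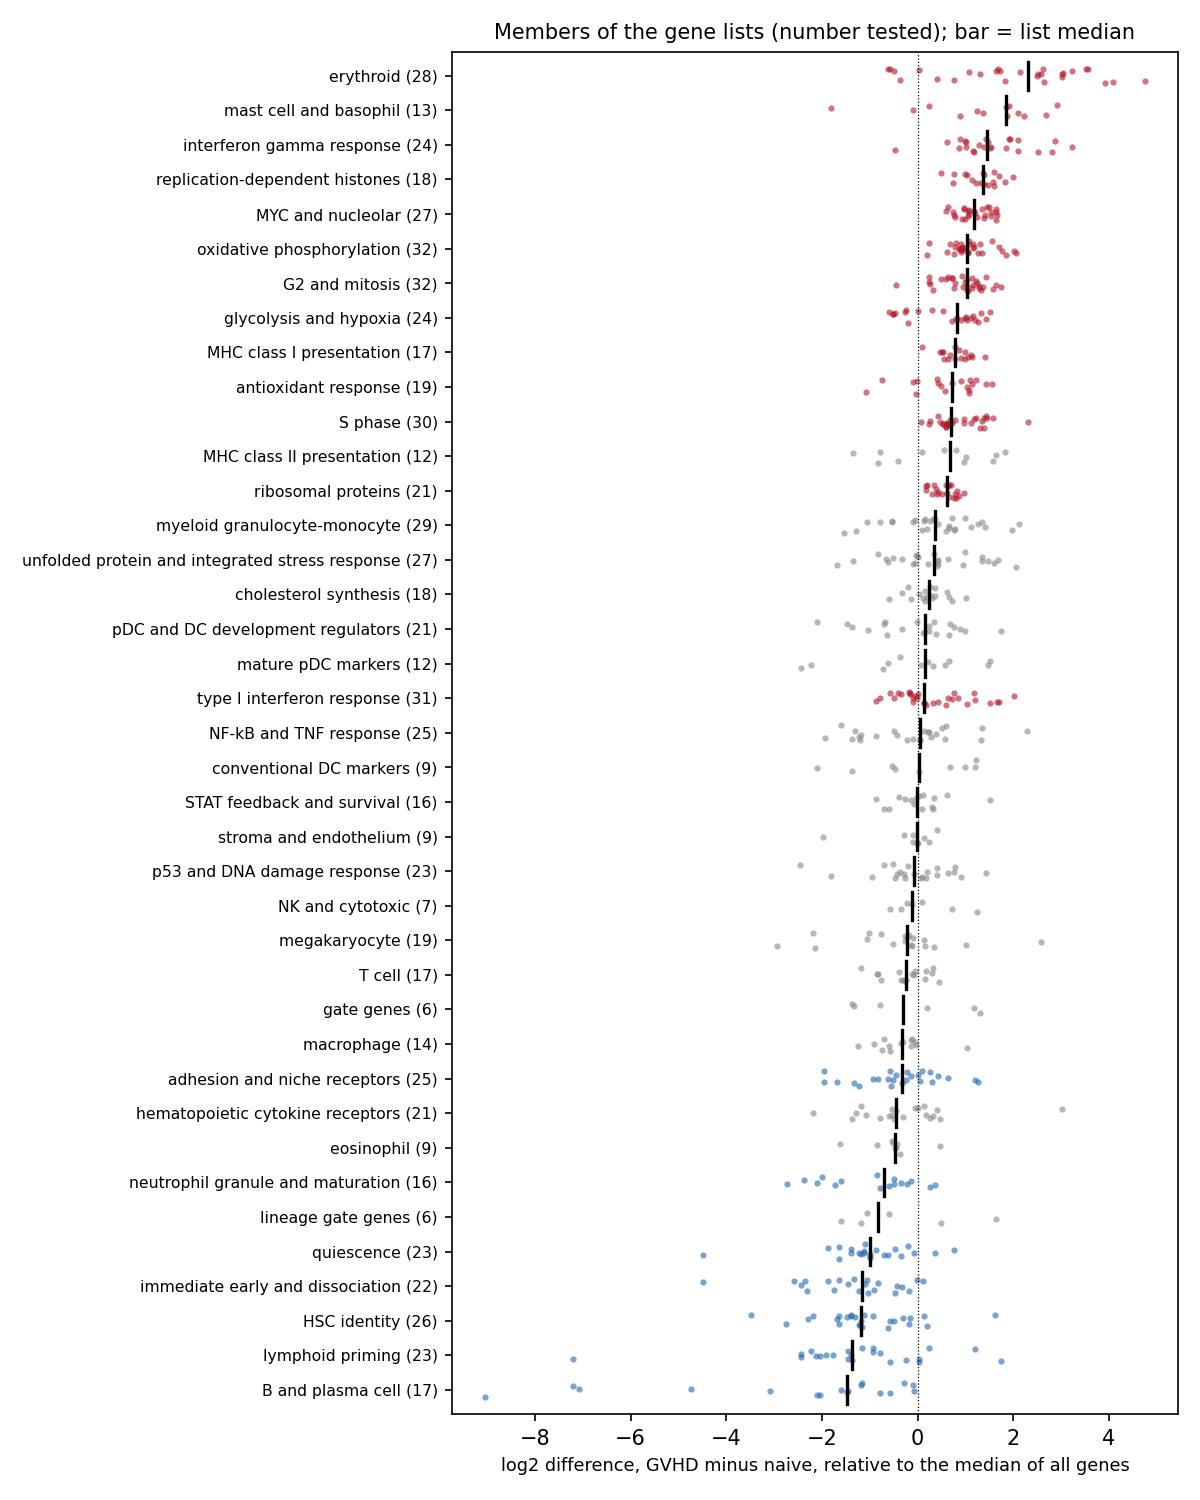
Log2 differences (x axis, GVHD minus naive, relative to the median of all genes) of the tested members of 39 gene lists (y axis, number tested in parentheses). Points are genes and black bars list medians; red and blue lists passed camera with a preset correlation as higher or lower in GVHD, and grey lists did not pass. The erythroid list had the highest median (2.32) and the B and plasma cell list the lowest (-1.47).

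HSC identity genes fell (median -1.19 over 26 members, adjusted p = 5.64e-10, but 0.581 with an estimated correlation). Adjusted over the list alone, 9 members were lower and 1 higher, none passed over all genes, and 17 were lower in both GVHD libraries than in every naive library. The stem cell transcription factor gene Hlf averaged 87.2 ± 25.99 FPKM in naive and 7.498 ± 5.80 in GVHD cells (adjusted p = 0.162). Mecom, which encodes the regulator Evi1, averaged 35.3 ± 2.59 and 6.38 ± 2.20 FPKM (adjusted p = 0.132), and Angpt1 and Fgd5 had log2 differences of -2.80 and -1.69. The quiescence list fell as well (median -1.001 over 23 members, adjusted p = 2.90e-08, but 0.581 with an estimated correlation), with 2 members past the threshold adjusted over the list alone. Its members with the smallest p-values were Nr4a1, Klf6, Ccng2 and Cdkn1c, the last encoding the cell cycle inhibitor p57, with log2 differences of -4.54, -1.91, -1.16 and -1.44. Without GVHD replicate 1 the quiescence median was -0.55, and without GVHD replicate 0 it was -1.52.

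Adhesion and niche receptor genes had a median of -0.33 over 25 members (adjusted p = 0.0236, but 0.711 with an estimated correlation). S1pr1, Procr, Robo4 and Tie1 had log2 differences of -2.00, -1.72, -1.27 and -1.99, and none passed when adjusted over the list alone. This list's median was 0.21 without GVHD replicate 1, where the call was lost, and -0.80 without GVHD replicate 0. The call was also lost without naive replicate 0 (adjusted p = 0.136) or naive replicate 1 (adjusted p = 0.0966).

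Immediate early genes, which are induced by stimulation and by cell handling, fell (median -1.16 over 22 members, adjusted p = 1.69e-10, but 0.581 with an estimated correlation). Adjusted over the list alone, 6 members were lower. Nr4a1, the member with the smallest p, averaged 168 ± 88.6 FPKM in naive and 6.29 ± 4.14 in GVHD cells (adjusted p = 0.0961). Egr3, Klf6 and Fosl2 had log2 differences of -2.49, -1.91 and -2.63. Nr4a1 and Klf6 also belong to the quiescence list. Without GVHD replicate 1 the list median was -0.67, and without GVHD replicate 0 it was -1.74.

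Lymphoid priming genes fell (median -1.37 over 23 members, adjusted p = 9.80e-08, but 0.581 with an estimated correlation), with 7 members lower and 1 higher when adjusted over the list alone. Dntt, the terminal transferase of lymphoid progenitors, averaged 13.7 ± 3.35 FPKM in naive and 1.65 ± 0.732 in GVHD cells (adjusted p = 0.152). Cd79a and Blnk, components of B cell receptor signalling, had log2 differences of -2.08 and -2.49. Ighm, the largest difference of the list at -7.24, is also a plasma cell transcript. Of the members, 20 had negative and 3 positive log2 differences. The latter were Ikzf1, Tcf3 and Bcl11a, at 1.75, 1.20 and 0.24 relative to all genes. Because Ighm, Cd79a and others also belong to the B and plasma cell list, these 2 calls are not separate results. Whether B-lineage RNA in the naive libraries gave the fall was not tested.

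The B and plasma cell list, a check for mature cells, had the lowest median of all lists (-1.47 over 17 members, adjusted p = 6.57e-11, but 0.581 with an estimated correlation), and 7 members fell when adjusted over the list alone. Igkc, the kappa light chain constant region, stood at 2159, 11311 and 7736 FPKM in the naive libraries and at 0.787 and 61.9 in the GVHD libraries (adjusted p = 0.216). Jchain, which joins secreted antibody, averaged 336 ± 216 and 1.15 ± 1.16 FPKM (adjusted p = 0.0525), Ighm averaged 2891 ± 2145 and 17.0 ± 13.5 FPKM, and Mzb1 had a log2 difference of -3.13. Of all tested immunoglobulin genes, those of the list included, 198 of 206 had lower values in GVHD, and 11 fell past the threshold adjusted over all genes. Igha, the IgA heavy chain constant region (chromosome 12, 113254830 to 113260236, mm10), averaged 95.1 ± 28.0 FPKM in naive and 0.925 ± 0.675 in GVHD cells (log2 difference -5.65 ± 0.43 SE, adjusted p = 0.0229), and its call was lost in 4 of the 5 fits that left out a library (highest adjusted p = 0.0664). Iglc3, a lambda constant region, averaged 151 ± 115 and 0.324 ± 0.0660 FPKM (adjusted p = 0.0379). Its call was lost in 10 of 17 other settings, among them each fit without a naive library, quantile normalization and upper quartile scaling. Variable segments that fell included Ighv6-3, Ighv1-26 and Ighv1-22, with adjusted p-values of 0.0232, 0.0328 and 0.0283, and reads of such near-identical segments can be split between copies. These calls were lost in 6, 8 and 7 of 17 other settings, in each case also without naive replicate 1. Igkv5-39, Ighv10-1 and Ighv1-53 averaged 200 ± 128, 59.2 ± 17.6 and 42.3 ± 18.5 FPKM in naive cells and were listed at 0 in both GVHD libraries.

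Neutrophil granule genes, also a check for mature cells, fell (median -0.70 over 16 members, adjusted p = 3.41e-05, but 0.581 with an estimated correlation). S100a9 averaged 460 ± 175 FPKM in naive and 87.8 ± 47.6 in GVHD cells, and S100a8, Ltf and Ngp had log2 differences of -2.77, -2.05 and -2.15. Adjusted over the list alone, 2 members passed. The median was -1.13 without GVHD replicate 0, and the call was lost without GVHD replicate 1 (median -0.51). The eosinophil, T cell, macrophage, stroma and endothelium, conventional DC and NK cell lists did not pass (adjusted p from 0.0590 to 0.961). Their most abundant members had log2 differences of -1.67 (Prg2), -0.16 (Lat), -1.28 (Apoe), -0.32 (Sparc), 1.17 (Cd24a) and 0.69 (Nkg7), none past the threshold.

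**Figure D3:**
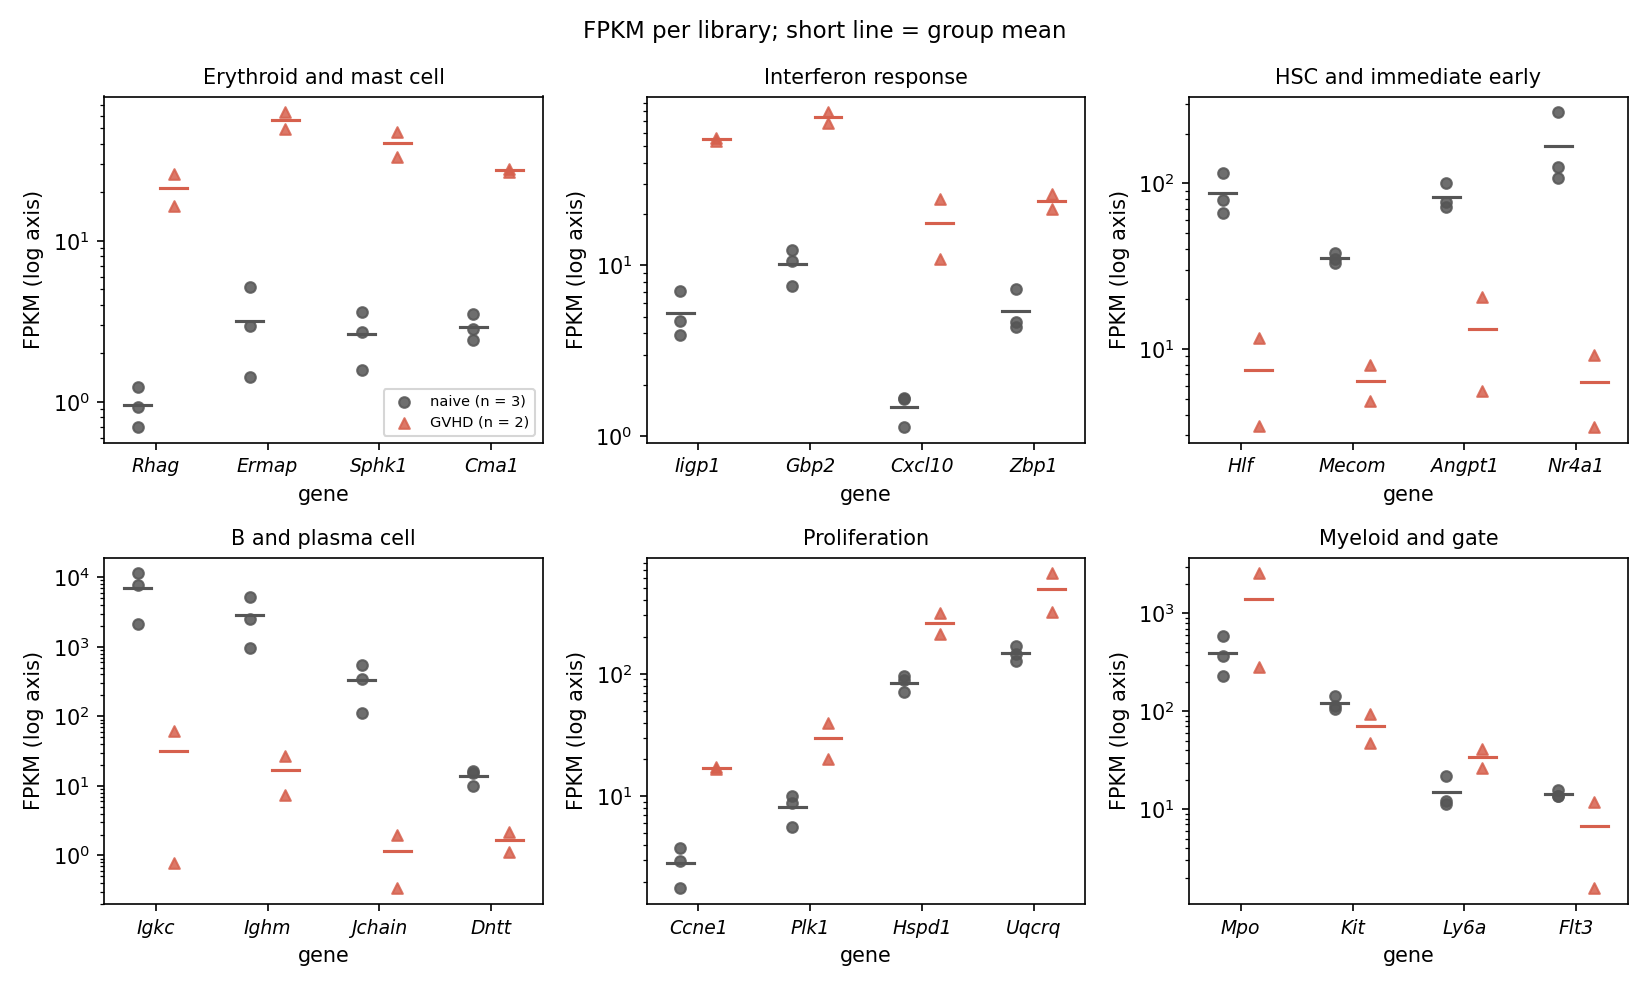
FPKM of 24 genes in each library (points, log axis; naive n = 3, GVHD n = 2) with group means as short lines, in panels by gene group. Igkc lay between 2159 and 11311 FPKM in naive libraries and at most at 61.9 in GVHD libraries, whereas Mpo stood at 2554 FPKM in GVHD replicate 0 and 282 in GVHD replicate 1.

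Genes of cell division rose. The G2 and mitosis list had a median of 1.03 over 32 members, with 26 higher in both GVHD libraries than in every naive one (adjusted p = 3.42e-12, but 0.581 with an estimated correlation). Ccnb1, the cyclin of mitotic entry, averaged 10.6 ± 2.52 FPKM in naive and 27.5 ± 0.413 in GVHD cells (adjusted p = 0.453), and Plk1, Cdca3 and Hmmr had log2 differences of 1.71, 1.53 and 0.99. The S phase list had a median of 0.70 over 30 members (adjusted p = 5.64e-10, but 0.604 with an estimated correlation). Ccne1, the cyclin of S phase entry, averaged 2.85 ± 1.01 and 16.9 ± 0.400 FPKM (adjusted p = 0.172) and was its only member past the threshold adjusted over the list alone. Rrm2, Cdc6 and Mcm10 had log2 differences of 1.54, 1.35 and 1.34. Replication-dependent histone genes had a median of 1.38 over 18 members (adjusted p = 9.02e-09, but 0.604 with an estimated correlation), and Hist2h2ac, Hist2h4, Hist1h1a and Hist1h1b had log2 differences of 1.55, 1.53, 1.28 and 1.94. No member of the G2 and mitosis or histone list passed when adjusted over the list alone. Without GVHD replicate 0 the medians of these 3 lists were 0.52, 0.35 and 0.85, and without GVHD replicate 1 they were 1.41, 1.20 and 1.78.

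All 27 tested MYC and nucleolar genes and all 32 oxidative phosphorylation genes had positive differences. The medians were 1.18 and 1.04 (adjusted p = 3.79e-14 and 2.19e-12, but 0.581 for both with an estimated correlation), and no member of either list passed when adjusted over the list alone. The chaperonin gene Hspd1 averaged 84.9 ± 12.8 FPKM in naive and 261 ± 71.2 in GVHD cells (adjusted p = 0.412), and Mrto4, Srm and Nhp2 had log2 differences of 1.36, 1.598 and 1.59. Uqcrq, a subunit of complex III, averaged 147 ± 20.3 and 490 ± 238 FPKM (adjusted p = 0.491), and Cox7b, Atp5g1 and Atp5b had log2 differences of 1.73, 2.01 and 1.81. Ribosomal protein, glycolysis and antioxidant genes had medians of 0.61, 0.81 and 0.72 (adjusted p = 0.00563, 0.0122 and 0.00234, but 0.711 for each with an estimated correlation), with no member past the threshold adjusted over the list alone. Among them, Rpl14, Rplp0, Rpl10a and Rpl8 had log2 differences of 0.71, 0.93, 0.74 and 0.76, and the glycolytic genes Ldha, Hk1, Eno1 and the lactate transporter gene Slc16a3 1.48, 1.38, 1.15 and 1.11. The antioxidant genes Gclc, G6pdx and Nqo1 had log2 differences of 1.05, 1.39 and 1.03, and Osgin1 one of -1.12. Without GVHD replicate 0 the MYC and oxidative phosphorylation medians were 0.67 and 0.49, the ribosomal protein, glycolysis and antioxidant medians were -0.20, -0.01 and 0.15, and the last 3 lists lost their calls. The MYC, oxidative phosphorylation, ribosomal protein and glycolysis medians were 1.67, 1.56, 1.19 and 1.25 without GVHD replicate 1. The ribosomal protein and glycolysis calls were also lost without naive replicate 2 (medians 0.25 and 0.53), as they were with the replicate block, which takes the same library out of the contrast, and after quantile normalization (0.19 and 0.63), and the ribosomal protein call with a filter at 5 FPKM (0.40) and after rescaling to equal sums (0.39).

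The lists closest to the series title did not pass. Regulators of pDC and DC development had a median of 0.16 over 21 members (adjusted p = 0.738), and mature pDC markers one of 0.15 over 12 members (adjusted p = 0.490). In both lists the mean difference was negative (-0.07 and -0.15). Of the 21 regulators, 12 had positive and 9 negative log2 differences, and none passed when adjusted over the list alone. In both GVHD libraries, 7 lay below and 2 above every naive library, where chance gives 10% of genes each way. Relative to all genes, Irf4, Runx2 and Tcf4 differed by -2.10, -1.47 and -0.64. The list median therefore does not mean that single regulators were unchanged. Ikzf1 averaged 45.1 ± 12.4 FPKM in naive and 148 ± 37.2 in GVHD cells, and Stat3 58.7 ± 14.3 and 62.5 ± 23.6. Among pDC markers, Dntt and Ly6d fell when adjusted over the list alone (log2 differences -2.48 and -2.27). Siglech, a pDC surface lectin, was at 1.30 ± 0.0957 FPKM in naive and 0.739 ± 0.286 in GVHD cells, and Bst2, which is also interferon-induced, at 10.2 ± 3.82 and 28.8 ± 7.01. Tlr9, Pld4, Lair1, Smim5 and Ly6c2 differed by 0.03, 0.27, 0.18, 0.54 and 0.61, Cox6a2 and Atp1b1 by -0.76 and -0.67, and Plac8 by 1.42 (620.5 FPKM in GVHD replicate 0 and 114 in GVHD replicate 1, and 0.21 without GVHD replicate 0), all on the log2 scale with adjusted p-values of at least 0.698.

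Of the genes used for the sort, Kit averaged 121 ± 20.8 FPKM in naive and 70.6 ± 32.2 in GVHD cells (adjusted p = 0.698) and Ly6a, which encodes Sca-1, 15.1 ± 5.86 and 33.8 ± 10.9 (adjusted p = 0.643). Flt3, which encodes CD135, stood at 13.7, 15.7 and 13.7 FPKM in the naive libraries and at 11.9 and 1.56 in the GVHD libraries. The myeloid list did not pass (adjusted p = 0.274), and the 2 GVHD libraries differed in it: Mpo and Elane were at 2554 and 1084 FPKM in GVHD replicate 0 and at 282 and 129 in GVHD replicate 1. Without GVHD replicate 0 its median turned from 0.35 to -0.76 and passed as lower (adjusted p = 4.75e-05), and without GVHD replicate 1 it was 1.34 and passed as higher (adjusted p = 1.39e-06). The megakaryocyte list did not pass (adjusted p = 0.0715), with Itga2b at 64.4 ± 30.1 and 66.4 ± 62.8 FPKM and Nfe2 at 64.6 ± 28.8 and 59.6 ± 49.4, but without GVHD replicate 0 its median was -1.29 and it passed as lower (adjusted p = 5.21e-04), as it did without naive replicate 2 (median -0.56). With all 5 libraries it also passed as lower with a filter at 5 FPKM, quantile normalization, upper quartile scaling, array weights or protein-coding genes alone (adjusted p = 0.00751, 0.0334, 0.0350, 0.0146 and 0.0404). Neither the NF-kB nor the p53 list passed (adjusted p = 0.342 and 0.503). Within them, Tnfaip2 averaged 23.03 ± 5.33 and 111 ± 2.33 FPKM, Nfkbia 45.7 ± 11.5 and 112 ± 12.1, Gadd45a had a log2 difference of 0.87, and Mdm2 averaged 33.3 ± 9.79 and 23.98 ± 0.0436 FPKM. The remaining lists did not pass either: hematopoietic cytokine receptors, unfolded protein response, cholesterol synthesis, STAT feedback and the sort and lineage genes had adjusted p-values of 0.102, 0.175, 0.283, 0.779, 0.815 and 0.262.

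Gene by gene, 72 of 23425 tested genes passed limma's moderated test at an adjusted p of 0.05, 38 higher and 34 lower in GVHD, all with an absolute log2 difference of at least 1. An unadjusted p of at most 0.05 was reached by 1810 genes, where chance alone gives 1171. The other 9 splits of the same libraries gave 296 to 2541 such genes, the most with naive replicate 2 and GVHD replicate 1 set against the rest. At the adjusted threshold, those 9 splits called 36 to 119 genes. Of the 72, 60 were listed at 0 in every library of 1 group, and 52 of the 70 with an annotated length were shorter than 200 nucleotides, against 2221 of 21604 tested genes (Fisher's exact p = 8.77e-37, two-sided). They included the 5S rRNA models n-R5s151, n-R5s71, n-R5s90 and n-R5s219 and the model RP23-350F7.6, listed at 0 in all naive libraries, and n-R5s28 and n-R5s19, listed at 0 in both GVHD libraries. Of the called genes, 6 were protein-coding, all higher in GVHD: Rhag, the short model Gm17428, the sodium pump subunit gene Atp1b2 (1.96 ± 0.423 and 30.1 ± 2.93 FPKM), the carboxylesterase gene Ces2g (2.26 ± 0.445 and 32.4 ± 4.35), the protease gene Hpn (1.51 ± 0.534 and 25.0 ± 3.11) and Add2 (1.84 ± 0.380 and 21.95 ± 2.82), which encodes an adducin of the red cell membrane skeleton. Their limma adjusted p-values were 0.0101 for Gm17428 and 0.0375 to 0.0493 for the other 5, each of which lost its call in all 5 fits that left out a library (adjusted p = 0.0613 to 0.215). No gene passed without naive replicate 1, 360 passed without GVHD replicate 0, and none passed with the replicate numbers as a block.

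A fit to the 12638 protein-coding genes alone, chosen after the data were seen, called 104 genes, 70 higher and 34 lower in GVHD, from the same FPKM values. It was not repeated without naive replicate 1, where the fit to all genes called 0, nor over the other splits of the libraries. Of the erythroid list, 15 members rose in this fit, among them Rhag, Ermap, Sphk1 and Ank1. Of the interferon gamma list 5 rose, among them Iigp1, Gbp2 and Cxcl10, and of the mast cell list 4. The HSC identity, immediate early and B and plasma cell lists each had 3 members that fell, including Hlf, Mecom, Angpt1, Nr4a1 and Jchain, as did 4 lymphoid priming genes including Dntt and Blnk. Without GVHD replicate 0 this fit called 82 genes, of which 41 were among the 104, and without naive replicate 2 it called 154, of which 95 were.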

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

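The fit to protein-coding genes alone was chosen after the data were seen. Of the 20 lists that passed, 13 passed in all 18 other fits with camera's preset correlation, the erythroid list with a median of 2.07 to 2.45 over the 5 fits that left out a library. None passed with an estimated correlation, and none by fry (0 lists in each case, against 20). The number of genes called moved far more. Against 72 (38 higher, 34 lower) it was 4 (3 and 1) with a pseudocount of 5, 45 (14 higher) with a filter at 5 FPKM, 38 (17 and 21) after quantile normalization, 37 (14 higher) after upper quartile scaling, 12 (9 and 3) with array weights, 0 in either direction with the replicate block, and 114 (57 lower) at a threshold of 0.1. The count of higher genes was 23 with no filter, 20 after rescaling to equal sums and 70 among protein-coding genes alone, and the count of lower genes was 56 with a pseudocount of 0.1. When each library was left out in turn, 0 to 360 genes were called (0 to 343 higher, 0 to 63 lower), with 0 called without naive replicate 1 and 360 without GVHD replicate 0. With a GVHD library left out, the remaining one is assumed to vary like the naive libraries. The cause of these shifts and of the reversals below was not tested, beyond the smaller number of genes or samples where that is the alternative itself. Only replicate numbers 0 and 1 occur in both groups, and deviations from the group mean correlated across genes by 0.19 for the libraries numbered 0 and by -0.08 for those numbered 1, so the numbers were not taken as pairs. The replicate block takes naive replicate 2, the only library with its number, out of the contrast, so its differences are those without that library and count as no separate evidence.

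Rescaling to equal sums and upper quartile scaling shifted the median of all genes by -0.47 and -0.13, a filter at 5 FPKM by 0.21, and gene values below are relative to the shift of the 2 scalings. Reversals were limited to genes and lists that had not passed, or to leaving out a library. Stat3 turned from 0.07 to -0.15 after rescaling to equal sums, -0.22 after quantile normalization, -0.00748 after upper quartile scaling, -0.0284 with array weights and -0.13 with the replicate block, and Ly6c2 turned to -0.0413 with array weights. The pDC regulator median turned to -0.0158 with a filter at 5 FPKM and -0.0852 after quantile normalization. The NF-kB median, 0.05, turned to -0.0655 after quantile normalization, -0.0794 with array weights, -0.0687 with the replicate block and -0.0378 among protein-coding genes. The p53 median, -0.08, turned to 0.085 with no filter, 0.0101 with array weights and 0.0169 with the replicate block. Over the fits that left out a library, medians ranged from -0.36 to 0.36 (pDC regulators), -0.28 to 0.24 (mature pDC), -0.76 to 1.34 (myeloid), -1.29 to 0.38 (megakaryocyte), -0.32 to 0.0718 (NF-kB), -0.12 to 0.20 (p53), -0.20 to 1.19 (ribosomal proteins), -0.0135 to 1.25 (glycolysis) and -0.80 to 0.21 (adhesion). Gene values ranged from -0.32 to 0.45 (Stat3), -0.38 to 2.80 (Mpo), -0.98 to 2.09 (Elane), -1.41 to 0.87 (Itga2b), -1.26 to 0.63 (Nfe2), -0.0638 to 0.0940 (Tlr9), -0.56 to 0.92 (Lair1), -0.72 to 1.94 (Ly6c2), -0.0102 to 0.55 (Pld4), -0.0292 to 1.10 (Smim5), -1.01 to 0.73 (Srgn), -0.63 to 0.31 (Lat), -0.73 to 2.10 (Nkg7), -2.67 to 0.10 (Apoe) and -1.10 to 0.47 (Sparc). Over all alternatives, 2216 of 2464 gene values and 446 of 540 list medians kept their direction and their side of the threshold. Most named genes had not passed in the first place, so this share says little about how stable a call is. A call was lost without a reversal in 170 gene values and 62 list medians. Lists that had not passed did so when a library was left out, besides the myeloid and megakaryocyte lists: eosinophil (adjusted p = 0.00118 without naive replicate 0), MHC class II (0.0414 without naive replicate 0), macrophage, cytokine receptor and STAT feedback (0.0284, 1.16e-06 and 0.0404 without GVHD replicate 0), macrophage and cytokine receptor also without naive replicate 2 (0.0360 and 0.0232), and T cell and unfolded protein response (0.0480 and 0.0301 without GVHD replicate 1), the last also without naive replicate 1 (0.0474). With all 5 libraries kept, the megakaryocyte list passed as lower in 5 fits, and the cytokine receptor list passed with a filter at 5 FPKM (0.00929), quantile normalization (0.0139), upper quartile scaling (0.0259), array weights (0.0144) and protein-coding genes alone (0.0388). The macrophage list passed with no filter (0.0467) and protein-coding genes alone (0.0390), the eosinophil list with a pseudocount of 5 (0.0449), no filter (0.0498), array weights (0.0467) and protein-coding genes alone (0.0195), and the unfolded protein list with no filter (0.0498). With the replicate block, the megakaryocyte, cytokine receptor and macrophage lists passed (0.00809, 0.0164 and 0.0056), as they did without naive replicate 2. Conversely, the ribosomal protein call was lost in 6 of 18 fits and the glycolysis call in 4, among them the replicate block (adjusted p = 0.0538 and 0.0849) and quantile normalization (0.436 and 0.0594). Depth is unknown, so values near 0 FPKM carry no counting error here.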

Other observations

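Outside the gene lists, the fit to protein-coding genes alone, chosen after the data were seen as were the genes named here, called both abundant metallothioneins, which bind zinc and copper, as higher in GVHD. Mt2 averaged 11.7 ± 7.55 FPKM in naive (n = 3) and 410 ± 181 in GVHD cells (n = 2), and Mt1 22.1 ± 9.85 and 273 ± 60.1 (limma adjusted p = 0.00374 and 0.00579 in that fit, 0.0623 and 0.0839 over all genes). Within the erythroid list, Klf1, the erythroid master regulator, averaged 2.16 ± 1.97 and 45.7 ± 6.30 FPKM, and Car1, a carbonic anhydrase of early erythroid cells, 9.70 ± 6.54 and 274 ± 167 (adjusted p = 0.00379 and 0.00374 in that fit, 0.1003 and 0.103 over all genes). Among genes that fell in it, the megakaryocyte list gene Mmrn1 averaged 18.5 ± 5.68 and 1.41 ± 0.0487 FPKM and Rgs2 99.3 ± 6.73 and 15.55 ± 10.7 (adjusted p = 0.00694 and 0.0262, and 0.0797 and 0.221 over all genes). Over the fits that left out 1 library, log2 differences ranged from 4.64 to 5.56 for Mt2, 3.41 to 3.96 for Mt1 and 3.76 to 4.52 for Klf1.

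Except for the tests over other splits of the libraries, the tests below were chosen after the results were seen. The 3 patterns that were followed up each remain a hypothesis found and tested on the same 5 libraries.

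Erythroid genes were higher in GVHD, with a list median of 2.32. Mature red cells carried into the sort would bring globin transcripts above all, but the median log2 difference of 4 globin genes was -0.51 (SD 0.80 over the 4), which argues against them, and the lineage gate would also remove most of them. Scalings that move all genes alike can hardly change a median relative to all genes, but after quantile normalization, which equalizes the distributions of the libraries, it was still 2.12, which argues against a difference of distribution that depends on expression level. Ly6a, which interferon induces and whose product is part of the gate, differed by 1.13 ± 0.44 SE, so erythroid and mast cell progenitors that gained Sca-1 may have entered the gate in GVHD. That explanation cannot be told apart from a change of expression within stem cells, because both predict the same bulk values.

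Immunoglobulin transcripts were lower in GVHD. Lymphoid-primed progenitors would not transcribe class-switched heavy chains, yet 5 class-switched constant region genes had a median log2 difference of -4.79 (SD 1.09 over the 5), so such progenitors alone are an unlikely source, although for Ighg2b and Ighg3 (adjusted p = 0.653 and 0.712) naive replicate 0 was at 2.17 and 0.162 FPKM, near the GVHD values. The gate should remove mature B-lineage cells too. Across the naive libraries, the plasma cell genes Sdc1 and Mzb1 ranked as Igkc, Jchain and Ighm did, replicate 1 highest and 0 lowest. Sdc1 stood at 3.81, 12.01 and 6.75 FPKM in naive replicates 0, 1 and 2, and Mzb1 at 8.61, 28.38 and 13.45. Prdm1 and Tnfrsf17 ranked alike at lower values, but Igha, Ighg1 and Ighg2c did not. Plasma cell RNA in the naive libraries is a possible source that was not tested, so the source is left open. The fall alone is no evidence of a change within stem cells, and whether GVHD caused it was not tested.

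Genes of respiration and nucleolar function were higher in GVHD, and ribosomal protein genes less so. The oxidative phosphorylation and MYC lists both lay at percentile 100 of 10000 random lists matched on mean expression, which argues against a shift of all genes of similar level, whereas the ribosomal protein list lay at percentile 71.4, which such a shift could give. Without GVHD replicate 0 the lower of the first 2 medians was 0.49, so how far that library sets their size cannot be told apart from the group difference with 1 library left. The ribosomal protein median was -0.20 without it, so a difference that this library alone carries would account for that list. GVHD replicate 0 is also the library with Y-linked transcripts, and sex was not tested as an explanation.

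The 5 libraries make 10 splits into 3 and 2, too few for a share under 0.05. For the number of genes called, 2 of the 10 splits reached the 72 of the real grouping, the real one included, and the highest other split called 119. That split set naive replicate 2 and GVHD replicate 1 against the rest, which points to a structure of the samples that crosses the groups. These libraries also had the most features at 1 FPKM or more (25083 and 24117, against 16828 to 21356 in the others). Whether that accounts for the split was not tested. The other splits called 66, 47, 62, 48, 68, 42, 48, 36 and 119 genes. For gene lists, 3 of the 10 splits reached the real count of 20, the real one included. In the same order, the other splits called 17, 19, 20, 8, 20, 16, 4, 2 and 17 lists. Counts of called genes and lists near the real ones therefore also arose from groupings that mix naive and GVHD libraries.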
